A study of Macaca mulatta with 23 samples.

How the data were processed

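RNA was measured on Affymetrix Rhesus expression arrays, which read each transcript with sets of short oligonucleotide probes. The samples were the CA1 field and the dentate gyrus (DG) of female rhesus macaques, from 6 young and 6 aged animals, and 23 arrays from 12 animals were analysed. Per the labels, the arrays were 6 CA1 arrays of young animals, 6 CA1 arrays of aged animals, 6 DG arrays of young animals and 5 DG arrays of aged animals. A DG array of animal 6 is not analysed here. Group, region, age and animal number were taken from the sample titles. The titles give animal 1 an age of 6.50 years for CA1 and 7.75 years for DG, while the ages of the other 10 animals with both arrays matched between regions.

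The deposited table holds MAS5 signal intensity on a linear scale for 52865 probe sets, and MAS5 is named in the submitters' processing notes, with its version not given in the sources used here. Read from the deposited values, every intensity was a whole number, and the mean after trimming 2% at each end lay between 500.027 and 500.036 on every array, so each array had been scaled to a common level. The presence calls mentioned in the series description were not used here. The median signal per array lay between 107 and 137, and 8 to 34 probe sets per array were listed at 0. These zeros were raised to a signal of 1 before log2 was taken, which departs slightly from the plan of using no floor, and no further normalization was applied. The number of arrays limits the precision of every value.

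Probe sets were named through the platform annotation, whose symbols were matched to current ones through gene identifiers. After 99 control probe sets were left out, 24956 probe sets had a single gene symbol, 361 had several and 27449 were unnamed here. No gene was named from a probe set with several symbols. The 14132 named genes were each represented by the probe set with the highest mean log2 signal over the 23 arrays. TTR and CALB1, which had been set down to be reported, had no named probe set and are not analysed here.

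All comparisons were fitted to log2 signals with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend, and p-values were adjusted by Benjamini-Hochberg over the probe sets tested. A probe set was tested when its signal exceeded the median of the array in at least as many arrays of the fit as the smaller group holds. Region was tested within the 11 animals that had both arrays, with the animal as a block, because the series description has both regions taken from the same hippocampus and tested in pairs. Age was tested separately in CA1 (6 young and 6 aged) and in DG (6 young and 5 aged), without covariates. Whether the age difference depended on region was tested on the CA1 minus DG difference of each of the 11 animals. All log2 changes are differences of mean log2 signal, and all p-values are two-sided. Comparisons with other divisions of the samples count only values as large as the real one or larger, and so are one-sided.

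As a check of the pairing, each array's deviation from its group mean was correlated between the CA1 and DG arrays of an animal. The correlation across probe sets lay between 0.149 and 0.478 in the 11 pairs, and in 9 of them an animal's CA1 array correlated best with its own DG array. The pair of animal 1, whose ages disagree in the titles, had the value of 0.478. Within groups, arrays correlated between 0.884 and 0.968 across probe sets, and no pair of arrays held identical values.

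There were 34 gene lists, 13 of cell type markers and 21 of pathways and complexes, fixed before the data were examined. Each list with at least 3 measured genes was tested with camera from limma at its preset correlation between genes of 0.01, which left 33 lists because only 2 red blood cell genes were measured. Camera was repeated with an estimated correlation, and fry, which asks whether a list's genes move on balance in a single direction and does not compare them with other genes, was run as a further test. Per list, the number of genes past an adjusted p of 0.05 over all probe sets is given together with the number adjusted over the list alone.

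The genes named in the text followed a rule fixed before the data were examined. For region it took the 10 largest changes in each direction among those past the threshold with a common sign in all 11 pairs, and for age it took up to 10 in each direction past the threshold, or the 5 with the smallest p where fewer than 5 passed, and for age by region the 5 with the smallest p in each direction. Of each cell type list and each list past the threshold it took up to 4 genes with the smallest p. GFAP, MBP, PROX1, WFS1, HBA and HBB were to be reported where tested. The text does not name every gene the rule gives: the part it names was picked after the values were seen, and the alternatives and the search for values far from their group cover that part only.

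Alternatives covered log2 of the signal plus 16, quantile normalization, a common 75th percentile for all arrays, no filter, a filter at the 75th percentile, array weights, eBayes without the intensity trend, a single probe set per gene, all 23 arrays with the animal as a random block, the region fit without the block, Spearman's rho for the correlation of age differences, and leaving out each animal in turn. The methods' t-test, which the series description names, was run on the same values, paired for region and unpaired for age. Further alternatives were added after the data had been seen: leaving out animals 3 and 5, leaving out animals 6 and 8, and the 3'/5' actin ratio of each array as a covariate. That ratio compares the signals of the 3' and 5' control probe sets of actin and rises as RNA is degraded or incompletely copied.

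The fits were tested on simulated values with the real means and spreads, in which 200 probe sets per comparison were changed. Among 26344 probe sets simulated for region, limma recovered 79.1% of 1.5-fold, 89.6% of 2-fold and 100% of 4-fold changes. For age in CA1, with 26535 probe sets, the recovered shares were 19.4%, 67.2% and 97.0%. For age in DG, with 26807 probe sets, they were 34.3%, 80.6% and 93.9%. For age by region, with 26344 probe sets, they were 13.4%, 49.3% and 93.9%. Of the calls in these simulations, 5.29% were false for region, 4.69% for age in CA1, 7.33% for age in DG and 10.3% for age by region, and all but age in CA1 lay above the nominal 5%. Each comparison was simulated a single time, with 10, 6, 11 and 12 false calls. These few calls cannot tell whether the false share of a comparison differs from the nominal rate. A simulated rise of 0.5 on the log2 scale in the oxidative phosphorylation list was called by camera in all 4 comparisons. In the age by region simulation, 1 unchanged list was called as well. The simulated noise was independent between probe sets, so these runs do not test how often camera calls unchanged lists when genes are correlated. In the real data, divisions of the animals other than the real one gave a median of 3 called lists for age in CA1, age in DG and age by region. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.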

Results

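Gene expression was measured in CA1 and the dentate gyrus, subregions of the hippocampus built around pyramidal neurons and granule cells respectively, in young and aged female rhesus macaques. The CA1 arrays came from 6 young animals with a mean age of 6.83 ± 0.54 years (SD) and 6 aged animals of 23.5 ± 1.74 years. The DG arrays came from 6 young animals and 5 aged animals, all of which also gave a CA1 array. The median MAS5 signal per array lay between 107 and 137. The first principal component, with 23.7% of the variance, mainly followed region, and on it the CA1 array of animal 3 (aged) lay among the DG arrays. The 3'/5' actin ratio, on the log2 scale, averaged 1.30 ± 1.08 (SD, n = 6) in CA1 of young animals, 1.19 ± 0.44 (n = 6) in CA1 of aged animals, 0.96 ± 0.24 (n = 6) in DG of young animals and 0.95 ± 0.28 (n = 5) in DG of aged animals. The CA1 array of animal 8 had the highest ratio, 3.43.

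The comparison of CA1 with DG asked which transcripts distinguish the subregions within an animal. CA1 had more MET, a receptor tyrosine kinase, by 5.31-fold (log2 change 2.41 ± 0.30 SE, n = 11 pairs), more of the homeobox factor MEIS2 by 3.70-fold, more of the secreted Wnt antagonist SFRP1 by 3.26-fold and more RGS4, a regulator of G protein signalling, by 3.40-fold. SH2D4B (6.06-fold), TSHZ2 (3.83-fold), RASL11B (3.31-fold) and STARD13 (3.08-fold) were also higher in CA1. DG had more of the tetraspanin TSPAN18 by 6.68-fold (log2 change -2.74 ± 0.34 SE), RTP5 by 5.82-fold, the serotonin receptor gene HTR7 by 4.40-fold, PMEL by 4.04-fold, the water and glycerol channel AQP3 by 3.66-fold, the neuropeptide Y receptor gene NPY2R by 3.30-fold and CIB2 by 3.06-fold. Each of these 15 genes had the same sign in 11 of 11 animals, which the rule for naming them required, with limma adjusted p between 7.08e-06 and 0.00107. Other probe sets passed with smaller log2 changes of -0.86 ± 0.19 for HTR7, 0.67 ± 0.13 for STARD13, 1.39 ± 0.28 for MET and 1.09 ± 0.33 for TSHZ2. The rule also gave KRT16 (log2 change 1.60) and PPP2R1B (1.54). Other probe sets had 1.51 ± 0.28 and -0.02 ± 0.14 for KRT16 and -0.07 ± 0.13 for PPP2R1B.

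Of 33 lists tested by region, camera called 6 higher and 2 lower in CA1, and 0 passed with an estimated correlation. Of 11 measured DG granule cell genes, 7 were lower and 1 was higher in CA1 over all probe sets tested, and 8 were lower and 1 higher adjusted over the list alone. They included PROX1, a transcription factor of granule cell identity (2.46-fold lower in CA1, in 10 of 11 animals), the synaptic C1q-related gene C1QL2 (2.24-fold lower, 11 of 11), STXBP6 (2.57-fold lower, 10 of 11) and AKAP7 (1.41-fold lower, 11 of 11), although another AKAP7 probe set had a log2 change of 0.18 ± 0.10 and another STXBP6 probe set -0.72 ± 0.15. As a list these genes were lower in CA1 (camera adjusted p = 0.00335, adjusted p = 0.497 with an estimated correlation). Of 9 CA1 pyramidal neuron genes, the transcription factor genes ETV1 (2.51-fold) and POU3F1 (3.05-fold) and the matricellular gene CCN3 (2.85-fold) were higher in CA1, 0 were lower, and the count adjusted over the list alone was also 3. The other ETV1 probe sets had log2 changes of 0.62 ± 0.14 and 1.19 ± 0.23. That list did not pass in camera (adjusted p = 0.161). WFS1 had a log2 change of -0.08 ± 0.07 (adjusted p = 0.455 in limma), and another probe set had -0.33 ± 0.07 (adjusted p = 0.00400).

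Markers of myelin and oligodendrocytes were higher in CA1, with 8 of 11 past the threshold, 0 lower, and 10 past it adjusted over the list alone. PLLP (2.11-fold), ENPP2 (2.02-fold) and UGT8 (1.95-fold) were examples. Another UGT8 probe set had a log2 change of 0.64 ± 0.25 and did not pass. The list's camera adjusted p was 0.00323 (adjusted p = 0.501 with an estimated correlation). MBP itself had a log2 change of 0.24 ± 0.09 with a limma adjusted p of 0.0502 on its brightest probe set, and 0.62 ± 0.15 with an adjusted p of 0.00707 on another. Without animals 3 and 5 its brightest probe set passed, at 0.36 ± 0.07 (limma adjusted p = 0.00185). Interneuron markers were higher in 4 of 7 genes, or 5 adjusted over the list alone, among them LHX6 (1.70-fold) and GAD2 (1.75-fold), the gene of a GABA-synthesizing enzyme, whose other probe set had a log2 change of 0.03 ± 0.14. The interneuron list had a camera adjusted p of 0.0246 (adjusted p = 0.497 with an estimated correlation). Microglia and macrophage markers were higher in 7 of 11 genes, or 8 adjusted over the list alone, including TYROBP (log2 change 0.58 ± 0.12) and CD14 (0.49 ± 0.10), with a camera adjusted p of 0.0246 (adjusted p = 0.497 with an estimated correlation). Endothelial and mural cell markers were higher in 6 of 12 genes, or 8 adjusted over the list alone, including CLDN5 and TEK, each 1.37-fold (another TEK probe set had a log2 change of -0.23 ± 0.27), with a camera adjusted p of 0.0183 (adjusted p = 0.497 with an estimated correlation). Among immature neuron genes SOX11 (2.18-fold) and DCX (1.44-fold) were higher in CA1, 2 others were lower, and the list as a whole did not pass (camera adjusted p = 0.86). Of the hemoglobin genes, HBA was 1.68-fold higher in CA1 in 11 of 11 animals, while HBB had a log2 change of 0.09 ± 0.16. GFAP, the astrocyte filament gene, had a log2 change of -0.15 ± 0.06 (limma adjusted p = 0.0756), and another probe set had 0.16 ± 0.07.

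Among other groups, genes of synaptic vesicles and release were lower in CA1, with 7 of 12 past the threshold, 0 higher, and 8 lower adjusted over the list alone. SLC17A7, the vesicular glutamate transporter, was 1.84-fold lower, SYN2 was 1.80-fold lower and PCLO, a presynaptic scaffold gene, was 1.70-fold lower, with a camera adjusted p of 0.00323 for the list (adjusted p = 0.497 with an estimated correlation). Complement genes were higher in CA1 in 5 of 11 cases, or 7 adjusted over the list alone, with CD55 at 1.82-fold (log2 change 0.87 ± 0.12), although its other probe sets had 0.47 ± 0.20 and 0.36 ± 0.14 and did not pass. C1QA was 1.32-fold higher on its brightest probe set and changed by -0.40 ± 0.11 on another. The complement list had a camera adjusted p of 0.0246 (adjusted p = 0.497 with an estimated correlation). Of 32 ribosomal protein genes, 17 were higher and 2 lower, or 18 and 3 adjusted over the list alone, with small changes such as RPS21 at 1.23-fold and RPS26 at 1.18-fold higher and RPL22 at 1.37-fold lower, where another RPL22 probe set had a log2 change of 0.05 ± 0.07. The ribosomal list had a camera adjusted p of 0.00836 (adjusted p = 0.501 with an estimated correlation) and did not pass after quantile normalization.

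In all, limma called 3989 probe sets higher and 4696 lower in CA1 of 26344 tested, and 540 of these differed by more than 2-fold. Which direction had more calls depended on scaling, with 4435 higher and 4281 lower after quantile normalization and 4632 higher and 4056 lower with a common 75th percentile. Called probe sets with the same sign in all 11 animals numbered 1034 higher and 1132 lower. Chance gives such agreement in 0.0977% of all probe sets, but a call itself favours agreement, so that share is no measure for called ones. The CA1 arrays of animals 3 and 5 had granule cell gene signals close to those of DG. PROX1 was at 11.29 and 11.06 there on the log2 scale, against 8.55 to 10.13 in the other CA1 arrays that had a DG partner. Without these animals the PROX1 log2 change was -1.61 ± 0.18 instead of -1.30 ± 0.24, and that of UGT8 was 1.32 ± 0.09 instead of 0.96 ± 0.21.

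**Figure D1:**
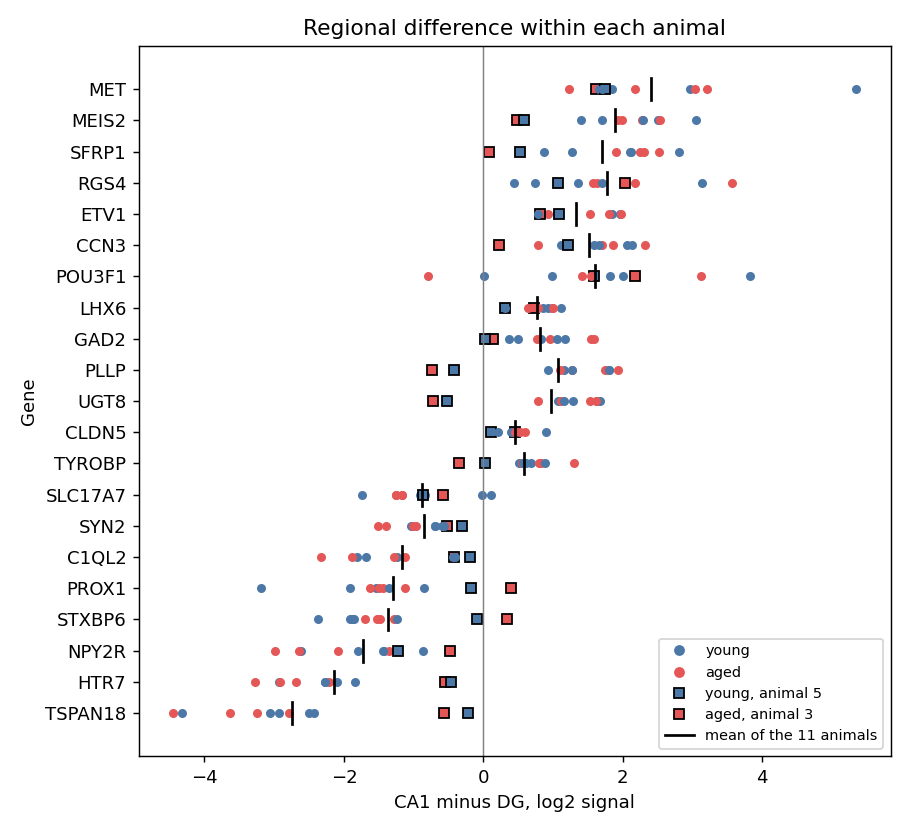
The CA1 minus DG difference in log2 signal (horizontal axis) is shown for 21 named genes, with a point per animal, blue for young and red for aged, and a black line at the mean of the 11 animals. Squares mark animals 3 and 5, whose differences lie near 0 for PROX1, TSPAN18 and STXBP6, while the means of these genes are -1.30, -2.74 and -1.36.

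The comparison of aged with young CA1 asked which transcripts differ with age in this field. Among named genes, ATP5MJ, which encodes a small subunit of ATP synthase, was 2.59-fold higher in aged CA1 (log2 signal 11.67 ± 0.17 SD, n = 6, against 10.30 ± 0.13, n = 6). QTRT1, a tRNA-modifying enzyme, was 1.98-fold higher, the hormone gene GHRL 1.97-fold and MAT2B, a regulatory subunit of S-adenosylmethionine synthesis, 1.85-fold. For each of these 4 genes all 6 aged arrays exceeded every young array, with limma adjusted p between 2.24e-05 and 0.0407. ATP5MJ and MAT2B passed in every other setting run, while the call was lost in 5 of 24 settings for GHRL and 13 of 24 for QTRT1. The other ATP5MJ probe set had a mean change of 0.11 on the log2 scale. No representative probe set of a named gene was lower past the threshold; the smallest p in that direction belonged to DMRTC1B (log2 change -0.95 ± 0.17, adjusted p = 0.0644) and CZIB (-0.51 ± 0.09, adjusted p = 0.0745), whose other probe sets ranged from -0.53 ± 0.18 to 0.07 ± 0.12. RPL13 had a log2 change of 0.55 ± 0.10 with an adjusted p of 0.0888, and its other probe sets had log2 changes of 0.46 ± 0.18, 0.47 ± 0.13 and -1.34 ± 0.34.

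Camera called 4 lists higher and 5 lower in aged CA1, while 0 passed with an estimated correlation and 2 in fry. In the MHC and antigen presentation list 12 of 16 genes had higher means in aged animals, 0 passed over all probe sets tested and 1 passed adjusted over the list alone. Its members included MAMU-DPA (log2 change 1.05 ± 0.28), MAMU-DRA (0.78 ± 0.27) and CD74 (0.53 ± 0.20), all of MHC class II, and its camera adjusted p was 0.0114 (adjusted p = 0.109 with an estimated correlation). Interferon response genes rose as a list with 17 of 20 positive and 0 past the threshold either way, including IFI27 (0.83 ± 0.30) and IFIT1 (0.49 ± 0.20), at a camera adjusted p of 0.0114 (adjusted p = 0.253 with an estimated correlation). Complement genes rose as a list with 0 of 11 past the threshold and 3 adjusted over the list alone, at an adjusted p of 0.0281 (adjusted p = 0.429 with an estimated correlation). The 3 genes of C1q, the starting protein of the classical pathway, had log2 changes of 0.80 ± 0.19 for C1QC, 0.72 ± 0.24 for C1QB and 0.56 ± 0.18 for C1QA, whose other probe set had 0.20 ± 0.23. Endothelial and mural cell markers rose as a list (0 of 12 past the threshold, also over the list alone, camera adjusted p = 0.0293, adjusted p = 0.253 with an estimated correlation), with CLDN5 at 0.34 ± 0.14 and VWF at 0.54 ± 0.25. The microglia list did not pass (camera adjusted p = 0.224), and its member with the smallest p, CD68, had a log2 change of -0.40 ± 0.10, while another CD68 probe set had 0.64 ± 0.20.

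Immature neuron genes fell as a list in aged CA1, with 0 of 8 past the threshold and 3 lower adjusted over the list alone. SOX11 and SOX4, transcription factors of newly formed neurons, had log2 changes of -0.54 ± 0.18 and -0.36 ± 0.12, and DPYSL3 had -0.29 ± 0.11. Other probe sets had -0.39 ± 0.26 for SOX11 and -0.13 ± 0.19 and -0.16 ± 0.20 for SOX4. The list's camera adjusted p was 0.0216 (adjusted p = 0.156 with an estimated correlation). Immediate early genes, which neurons induce on activity, fell as a list (0 of 13 past the threshold, also over the list alone) with EGR4 at -0.65 ± 0.25 and ARC at -0.56 ± 0.33, at a camera adjusted p of 0.0352 (adjusted p = 0.253 with an estimated correlation). That call was lost with the 3'/5' actin ratio as a covariate. Synaptic vesicle genes fell as a list with 12 of 12 negative, 0 past the threshold either way and SV2B at -0.38 ± 0.14, at an adjusted p of 0.0459 (adjusted p = 0.516 with an estimated correlation). Calcium handling genes fell as a list with 12 of 15 negative and the calcium release channel gene ITPR1 at -0.38 ± 0.22, at an adjusted p of 0.0345 (adjusted p = 0.516 with an estimated correlation). Oxidative phosphorylation genes fell as a list with 35 of 45 negative and COX7A2 at -0.17 ± 0.08, at an adjusted p of 0.0293 (adjusted p = 0.516 with an estimated correlation), and in both of these lists 0 genes passed over all probe sets or over the list alone. The fixed markers GFAP (0.07 ± 0.08), MBP (-0.02 ± 0.11), PROX1 (0.34 ± 0.37), WFS1 (-0.04 ± 0.12), HBA (-0.81 ± 0.45) and HBB (-0.52 ± 0.22) did not pass in limma.

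Of 26535 probe sets tested in CA1, limma called 13 higher and 4 lower, 11 of them unnamed here. At an unadjusted p under 0.05 limma had 2193, where 1327 are expected by chance, and the methods' t-test called 12 after adjustment. With all 23 arrays and the animal as a random block, limma called 180. Leaving out an animal moved the count of 17 to 38 (animal 8), 27 (animal 11) or 11 (animal 2 or 12), and the count of 9 lists to 2 (animal 11) or 5 (animal 2 or 12).

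The comparison of aged with young DG asked the same question in the dentate gyrus. ATP5MJ was again higher in aged animals, by 2.72-fold (log2 signal 11.63 ± 0.07 SD, n = 5, against 10.18 ± 0.15, n = 6), and GHRL (2.01-fold), QTRT1 (1.85-fold) and MAT2B (1.45-fold) were higher as in CA1. Also higher were the mismatch repair gene PMS2 (3.34-fold), the RNA-binding protein gene ELAVL1 (2.24-fold), SEPTIN8 (1.84-fold), PCDHA11 (1.84-fold), JPT2 (1.71-fold) and RPL13 (1.57-fold). Lower in aged DG were the olfactory receptor gene OR4X2 (2.65-fold), LTBP1 (2.07-fold), a binding protein of latent TGF-beta, NOL8 (1.45-fold) and PAIP1 (1.35-fold). All 5 aged arrays lay outside the range of the young arrays for each of these 14 genes, with limma adjusted p between 2.25e-06 and 0.0494. Only ATP5MJ passed in every other setting run, PMS2, GHRL, SEPTIN8 and PCDHA11 lost their calls in 1 to 4 settings, and the other 9 genes lost theirs in 12 to 18 of 23 or 24. Other probe sets of these genes moved less or the other way, with mean log2 changes of 0.12 for ATP5MJ, 0.05 for SEPTIN8, -0.04 for PAIP1 and -0.30 for NOL8. The other RPL13 probe sets went both ways, with -0.09 ± 0.23, -1.56 ± 0.36 and 0.47 ± 0.09. PMS2, PCDHA11, OR4X2 and RPL13 belong to families with similar gene copies, and which copy their probes read is uncertain.

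Markers of myelin and oligodendrocytes rose as a list in aged DG, with 10 of 11 positive, 0 past the threshold over all probe sets and 3 adjusted over the list alone. The gap junction gene GJB1 had a log2 change of 0.99 ± 0.20, UGT8 0.88 ± 0.31 and MBP 0.24 ± 0.09, and the list's camera adjusted p was 8.5e-05 (adjusted p = 0.463 with an estimated correlation). Lipid transport and storage genes rose as a list, with 0 of 12 past the threshold, 5 higher and 1 lower adjusted over the list alone, at an adjusted p of 0.00658 (adjusted p = 0.463 with an estimated correlation). They included the lipocalin APOD (0.57 ± 0.12), the lysosomal cholesterol transporter NPC1 (0.45 ± 0.11) and PLTP (0.36 ± 0.09). Genes of glycolysis and the TCA cycle rose as a list with 20 of 23 positive and 0 past the threshold either way, with IDH1 at 0.32 ± 0.10 (0.16 ± 0.16 on another probe set) and ENO1 at 0.17 ± 0.08, at an adjusted p of 0.00469 (adjusted p = 0.463 with an estimated correlation). The MHC and antigen presentation list rose with 13 of 16 positive and 0 past the threshold either way, with MAMU-DRA at 1.28 ± 0.40 and CD74 at 0.55 ± 0.18, at an adjusted p of 0.0127 (adjusted p = 0.463 with an estimated correlation). Antioxidant genes rose as a list (0 of 13 past the threshold, 2 adjusted over the list alone), with mitochondrial SOD2 at 0.55 ± 0.16 (0.20 ± 0.18 on another probe set) and PRDX3 at 0.27 ± 0.08 (0.10 ± 0.17, 0.15 ± 0.26 and 0.24 ± 0.11 on others), at an adjusted p of 0.0440 (adjusted p = 0.463 with an estimated correlation).

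Other markers in DG did not pass in limma. SOX4 had a log2 change of -0.43 ± 0.11 (adjusted p = 0.136), with -0.09 ± 0.16 and -0.20 ± 0.16 on other probe sets, and the immature neuron list had a camera adjusted p of 0.0759. The interneuron genes PVALB and NPY differed in sign (0.55 ± 0.15 and -0.51 ± 0.19), and their list did not pass (camera adjusted p = 0.76). The fixed markers had log2 changes of 0.17 ± 0.09 for GFAP, -0.11 ± 0.16 for PROX1, -0.00064 ± 0.09 for WFS1, -0.12 ± 0.46 for HBA and -0.19 ± 0.28 for HBB.

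Of 26807 probe sets tested in DG, limma called 34 higher and 23 lower, 29 of them unnamed here. The methods' t-test called 8 after adjustment and 2988 at an unadjusted p under 0.05, where 1340 are expected by chance. The count of 57 became 24, 18, 21, 27, 34, 35, 17 and 28 without animals 1, 2, 3, 4, 8, 9, 10 and 12, and the count of 5 lists became 8 without animal 8.

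**Figure D2:**
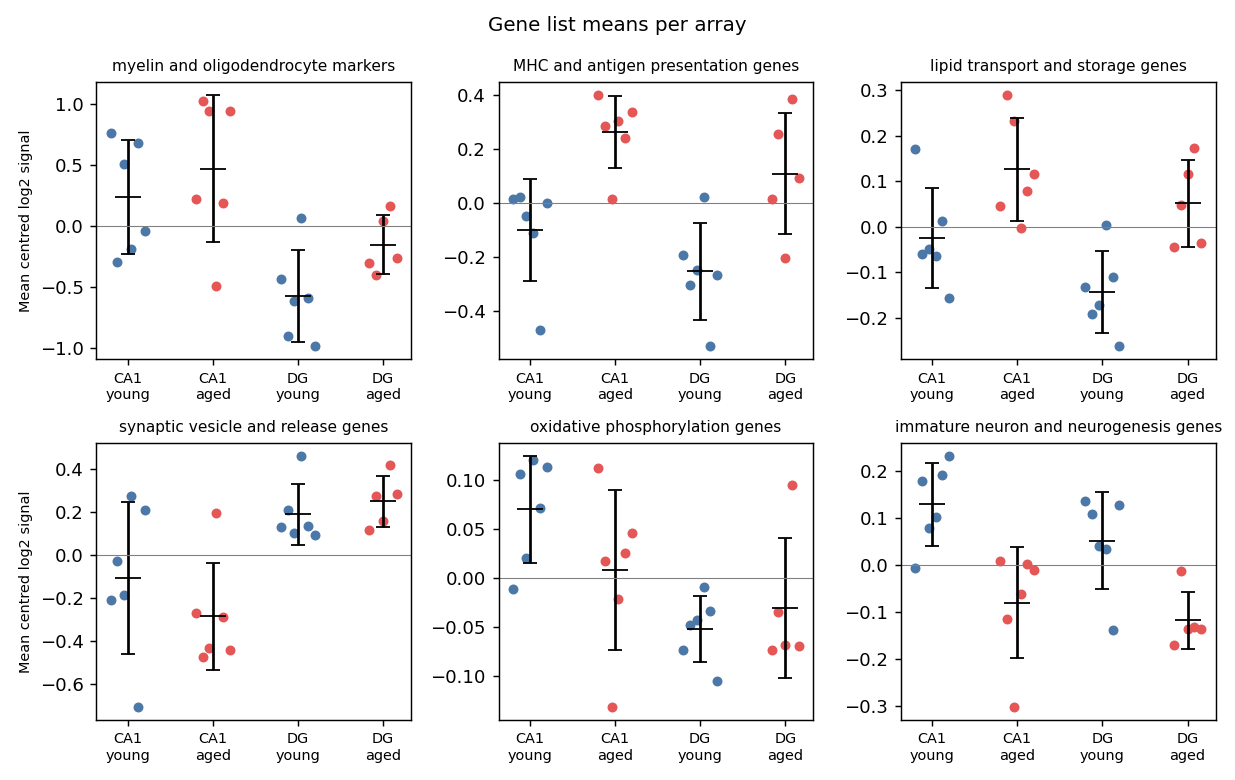
Each panel gives, for a gene list, the mean over its genes of log2 signal centred on the gene's mean over all 23 arrays (vertical axis), with a point per array, grouped by region and age, and black bars for the group mean ± SD. The MHC and antigen presentation list is higher in aged animals in both regions, and the myelin list is higher in CA1 than in DG.

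Probe sets named for the mitochondrial genome had the largest age differences in both regions, and were singled out after their values were seen. Mitochondrial probe set 6 was 212-fold higher in aged CA1 (log2 signal 15.40 ± 0.28 SD, n = 6, against 7.68 ± 1.19, n = 6) and 176-fold higher in aged DG (15.63 ± 0.48, n = 5, against 8.17 ± 1.25, n = 6). Mitochondrial probe set 3 was 66.3-fold higher in aged CA1 and 64.3-fold in aged DG, with limma adjusted p of 9.87e-06 and 6.12e-05. Aged signals of both sets lie near the highest signals of the arrays (15.39 to 16.07 on the log2 scale), and some young signals of set 6 lie near the array median, so these folds are approximate. Mitochondrial probe set 10 was 18.6-fold and 16.9-fold higher and did not pass (adjusted p = 0.0652 in CA1, and in DG an unadjusted p of 0.000109, which adjustment left just above the threshold). By contrast, probe sets 4 and 12, at log2 signals near the top of the array range in all groups, had age changes of -0.06 ± 0.16 and -0.10 ± 0.11 in CA1 and 0.11 ± 0.19 and 0.10 ± 0.09 in DG. Probe set 13 changed by 0.94 ± 0.34 in CA1 and -0.04 ± 0.29 in DG.

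**Figure D3:**
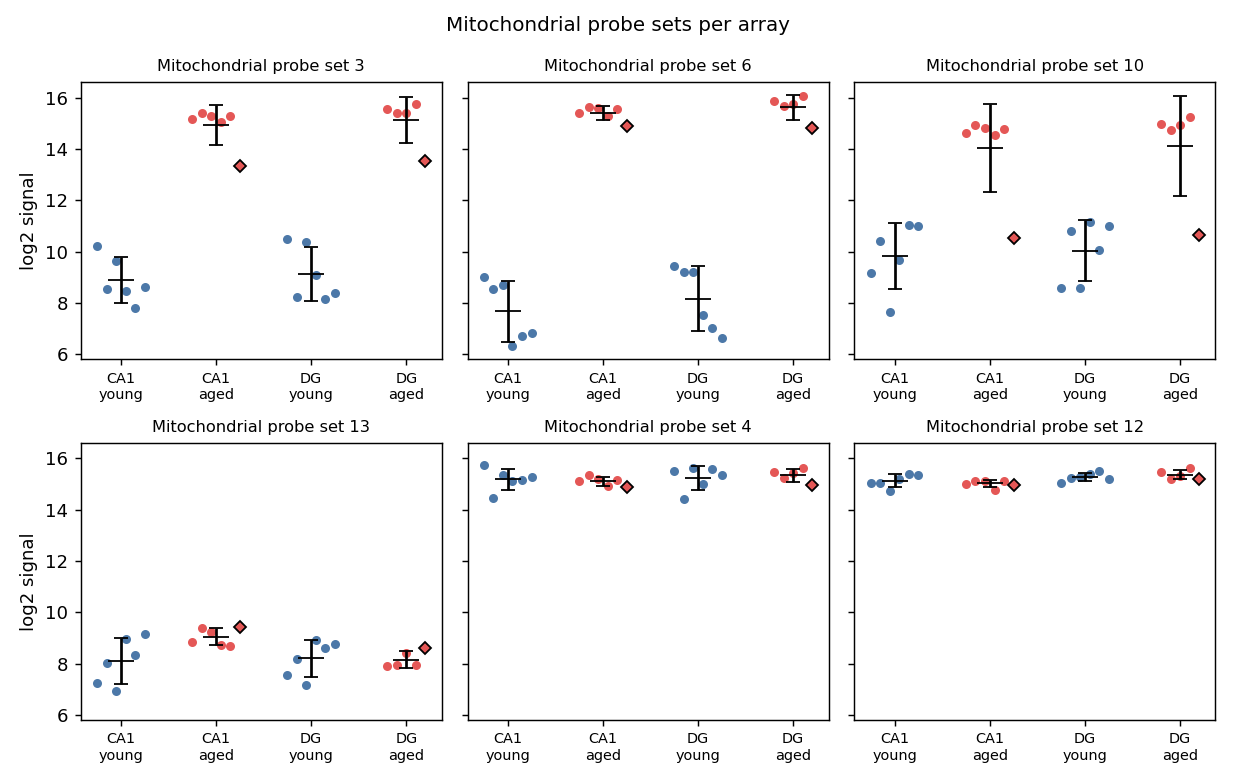
Log2 signal (vertical axis) of 6 mitochondrial probe sets is shown with a point per array, blue for young and red for aged, grouped by region and age, with black bars for the group mean ± SD. Probe sets 3, 6 and 10 are higher in aged animals in both regions, and animal 11, drawn as a diamond, is at 10.5 in CA1 and 10.6 in DG on probe set 10, among the young animals.

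Age differences in the subregions resembled each other. Across 25911 probe sets in the 11 animals with both arrays, the log2 changes correlated with a Pearson r of 0.644 and a Spearman rho of 0.539, and 68.4% had the same sign. Without the filter on signal r was 0.234. This correlation is across probe sets, which are not independent replicates, and both regions came from the same animals. Over 100 divisions of the 11 animals into 6 and 5, the real one included, the median r of the others was 0.357 and the highest 0.612, and the covariance was 0.0476 for the real ages against a median of 0.0169 and a highest value of 0.0451. Mitochondrial probe sets 3, 6 and 10, with very large changes in both regions, were part of these values. No run left them out, so how much of the narrow lead over the highest other division rests on them was not tested. Calls shared by both regions numbered 11 higher and 2 lower of 25740 probe sets tested in both. They included ATP5MJ, GHRL, MAT2B and QTRT1, mitochondrial probe sets 3 and 6, and other probe sets unnamed here. With the 11 animals that gave both arrays 12 calls were shared, against at most 1 in any other division drawn.

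Whether age differences depended on region was tested within animals. At the level of lists, 5 had lower CA1 minus DG differences in aged than in young animals. These were oxidative phosphorylation (37 of 46 genes negative, camera adjusted p = 0.00315), synaptic vesicle and release (11 of 12, adjusted p = 0.00703), glycolysis and the TCA cycle (18 of 23, adjusted p = 0.0115), calcium handling (12 of 15, adjusted p = 0.0254) and ribosomal proteins (24 of 32, adjusted p = 0.0435), and each had an adjusted p = 0.713 with an estimated correlation. In each of these lists 0 genes passed over all probe sets or adjusted over the list alone. Members with the smallest p included SYN2 (-0.43 ± 0.17), SV2B (-0.44 ± 0.22), CALM3 (-0.32 ± 0.13), ATP5MC3 (-0.23 ± 0.10), NDUFS3 (-0.27 ± 0.13), ENO1 (-0.18 ± 0.09), PKM (-0.19 ± 0.10) and RPL4 (-0.32 ± 0.15). Other probe sets of SYN2, CALM3, ENO1 and PKM were also negative, most of them closer to 0. Of single probe sets, limma called 0 of 26344, with 713 at an unadjusted p under 0.05 where 1317 are expected by chance. The methods' t-test called 0 after adjustment and 860 at an unadjusted p under 0.05. Among named genes the smallest p for positive differences belonged to LOC712599 (0.84 ± 0.18) and SGF29 (0.99 ± 0.21), and for negative ones to MYCBPAP (-1.81 ± 0.44) and FHL2 (-0.78 ± 0.20), all with adjusted p = 1.00. After quantile normalization 0 lists passed, and the count of 5 lists became 1, 3, 8 and 2 without animals 2, 3, 5 and 12.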

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

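The tests reported here on the mitochondrial probe sets, on DG shares from genes higher in DG and on single genes of animals 3 and 5 were chosen after the values had been seen. The run with an estimated correlation between genes was planned, but its use as a test of an explanation was chosen after its result was seen, and the runs without animals 3 and 5 or with the 3'/5' actin ratio were also added after the data had been examined. Of 180 groups of 5 or 6 arrays tested for a value far from the rest, 13 had one, and chance gives about 1 in 20 of such groups.

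The largest pattern is the age difference of mitochondrial probe sets 3, 6 and 10 in both regions. More mitochondrial RNA in aged animals would raise other mitochondrial probe sets that follow it. Probe set 13 changed by at most 0.94 on the log2 scale (± 0.34 SE, in CA1). That was below the least of the changes of 3, 6 and 10 by 3.28 ± 0.82 in CA1 and 4.12 ± 0.82 in DG. However, probe set 13 read low signals, with group means of 8.11 to 9.05, and its transcript was not identified here. Whether it follows mitochondrial RNA as a whole is not known, so this test argues only weakly against that explanation. A first version of this test, also written after the values were seen, used probe sets 4 and 12, whose changes of -0.10 to 0.11 were small, and it was replaced because they lie near the top of the signal range and could hide a rise. Sequence differences between animals under the probes remain a candidate explanation: deviations from the group mean on probe set 10 were shared by an animal's CA1 and DG arrays with r = 0.90 over 11 animals, but other lasting properties of an animal would give this too, and age itself is not separated from the ancestry of the age groups in this design.

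That correlation on probe set 10 rests on animals 11 and 5. Spearman's rho was 0.482 (permutation p = 0.137, adjusted p = 0.137, against p = 0.00228 for r), and without these 2 animals r was 0.555. On probe set 3 r was 0.943 (permutation p = 3e-05, adjusted p = 9e-05) with rho 0.918 (p = 0.00016, adjusted p = 0.00048) and 0.896 without the 2 farthest animals, and on probe set 6 r was 0.917 (permutation p = 0.00022, adjusted p = 0.00033) with rho 0.882 (p = 0.00072, adjusted p = 0.00108) and 0.963 without the 2 farthest. Adjustment was over these 3 relations. The permutations shuffled all 11 animals without regard to age group. On probe set 6 the SD was 1.19 in CA1 and 1.25 in DG of young animals, against 0.28 and 0.48 in aged animals. Its permutation p-values may therefore be too small. Animal 11, an aged animal, stood apart from the other aged arrays on probe set 3, at 13.36 in CA1 (others 15.04 to 15.41) and 13.53 in DG (others 15.40 to 15.76), and on probe set 10, at 10.54 in CA1 (others 14.56 to 14.95) and 10.63 in DG (others 14.75 to 15.26).

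The CA1 arrays of animals 3 and 5 carried high granule cell gene signals, and PROX1 of animal 3, at 11.29 against 9.49 to 10.13 in the other aged CA1 arrays, stood far from its group. DG tissue in these CA1 dissections may account for part of it: from up to 100 genes higher in CA1, chosen without the animal in question, a linear mixing estimate put the DG share at 0.809 in animal 3 (quartiles over genes 0.656 and 0.965) and 0.805 in animal 5 (0.649 and 0.985), against -0.295 to 0.29 in the other CA1 arrays with a DG partner. From genes higher in DG the shares were 0.583 and 0.613, against -0.235 to 0.118. Single genes differed in how far they followed such a share. MEIS2 had CA1 minus DG differences of 0.49 and 0.59 in animals 3 and 5 (mean of the others 2.19). SFRP1 had 0.08 and 0.53 (others 2.02) and RASL11B 0.36 and 0.26 (others 2.04). DCX kept 0.57 and 0.52 (others from 0.26 to 0.80). UGT8 reversed to -0.72 and -0.53 (others from 0.79 to 1.68), below what DG tissue alone would give. SH2D4B had 3.05 and 2.97 and POU3F1 2.18 and 1.58. The other animals ranged from 0.43 to 4.86 and from -0.79 to 3.82 on these genes, so their values say little. An exchange of an animal's CA1 and DG arrays is argued against by the DG arrays of animals 3 and 5, whose DG shares were 1.03 and 1.11 as for other DG arrays.

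Tissue of another kind in these samples was not tested. MBP at 14.68 (others 15.19 to 15.32) and SOX11 at 8.77 (others 9.33 to 9.66) were low in the young CA1 array of animal 5.

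Age changes differed between CA1 and DG for 5 gene lists in camera, with adjusted p of 0.00315 for oxidative phosphorylation, 0.00703 for synaptic vesicle and release, 0.0115 for glycolysis and the TCA cycle, 0.0254 for calcium handling and 0.0435 for ribosomal protein genes. Correlation between genes of a list could account for these calls, but this was not settled. With an estimated correlation in camera 0 lists passed, each with an adjusted p of 0.713. That run also called 0 lists by region, where its lowest adjusted p was 0.497, so its 0 here cannot decide the matter. After quantile normalization 0 lists passed, and 21 of 100 divisions of the animals gave 5 lists or more. RNA degradation measured by the 3'/5' actin ratio was not decided. With that ratio as a covariate 4 lists stayed past the threshold. The covariate was the CA1 minus DG difference in the ratio, and animal 8 dominated it, with 3.43 in CA1 and 0.93 in DG. That run therefore says little about degradation in the other animals. DG tissue in CA1 dissections of animals 3 and 5 was not decided as a cause, since 3 lists stayed without them and leaving out a single animal gave anything from 1 to 8. These animals are 1 aged and 1 young, with similar DG shares of 0.809 and 0.805. Such tissue would thus be present in both age groups. A difference in ageing between regions stays open, as limma called 0 single probe sets and the list calls do not settle it.

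Single values far from their group were MAT2B in the aged CA1 array of animal 3 (12.13, others 11.63 to 11.80), C1QC in the young CA1 array of animal 12 (8.40, others 9.05 to 9.30), EGR4 in the aged CA1 array of animal 11 (7.87, others 8.59 to 9.02) and NPC1 in the young DG array of animal 5 (10.19, others 9.65 to 9.80). The CA1 minus DG difference of MYCBPAP was 3.22 in young animal 12 (others 0.41 to 1.17). The log2 3'/5' actin ratio of the young CA1 array of animal 8 was 3.43 (others 0.698 to 1.41).

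Other divisions of the samples were drawn 100 at a time, the real one included. For region, with CA1 and DG exchanged in some animals, only 1 division, the real one, gave 8685 calls or more, and the highest other gave 5457. For lists by region, 7 divisions gave 8 or more, with a highest of 10, so chance is not excluded for the number of lists. A division that exchanges few animals keeps much of the real region difference, so these list counts are not a clean measure of chance. For age in CA1, 2 divisions gave 17 calls or more, the real one and another with 219. What set that other division apart was not tested. With the 11 animals that gave both arrays, the real ages gave 15 calls in CA1 and the highest other division 604. For lists in CA1, 7 divisions gave 9 or more, with a highest of 11. For age in DG, 1 division gave 57 calls or more, with 38 as the highest other, while 32 divisions gave 5 lists or more, with a highest of 13. For age by region, all 100 divisions gave 0 calls or more, with a highest of 122, and 21 gave 5 lists or more, with a highest of 12. Under 5% of the drawn divisions reached the real counts of probe sets for region and for age in DG. That argues against chance for these counts without excluding it, as 100 divisions can give no share below 1 in 100. The count for age in CA1 was also under 5%, but a division not by age gave more calls than age itself. Chance is therefore not firmly excluded for CA1. For each of the 4 counts of lists 5% or more of the divisions did as well, so chance is not excluded. These shares were not adjusted over the counts tested. For the correlation of age differences between regions, 1 division, the real one, reached 0.644, and the highest other was 0.612. That correlation included mitochondrial probe sets 3, 6 and 10, and no run left them out.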

How the results depend on the processing

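Chosen after seeing the data were the runs without animals 3 and 5, without animals 6 and 8, and with the 3'/5' actin ratio as a covariate. The cause of the changes below was not tested, except that a stricter filter and a single probe set per gene test fewer probe sets. For region, the count of 8685 was 5340 with the stricter filter and 3597 with a single probe set per gene, and it stayed within 1.5-fold elsewhere, with 6452 without the replicate block, which also gave 7 lists in place of 8. The 8 region lists became 4 with the stricter filter, 0 with an estimated correlation and 23 in fry. For age in CA1, 17 became 7 with the stricter filter, 48 with array weights, 4 with a single probe set per gene, 2195 in the methods' t-test at an unadjusted p of 0.05, 180 with the animal as a random block over 23 arrays, 27 without animals 6 and 8, 42 with the actin ratio, and 11 to 38 leaving out each animal. The 9 lists became 4 with the stricter filter, 0 with an estimated correlation, 2 in fry, and 2 to 11 leaving out each animal. For age in DG, 57 became 22 without a filter, 104 with array weights, 34 without the intensity trend, 8 in the methods' t-test after adjustment and 2988 before it, 9 with a single probe set per gene, 26 without animals 3 and 5, 34 without animals 6 and 8, 104 with the actin ratio, and 17 to 83 leaving out each animal. The 5 lists became 8 without a filter, 0 with an estimated correlation, 0 in fry, 8 without animals 6 and 8, and 4 to 8 leaving out each animal. For age by region, 0 probe sets passed in limma in every setting run, against 860 in the methods' t-test at an unadjusted p of 0.05; the 5 lists became 0 with quantile normalization, an estimated correlation or fry, 2 with array weights, 3 without animals 3 and 5, and 1 to 8 leaving out each animal. The correlation of age effects was 0.234 without a filter and 0.581 to 0.673 leaving out each animal.

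The median difference of the ribosomal protein list for age by region, which had passed, turned from -0.06 to 0.00327 with quantile normalization. The other turned signs were of genes that had not passed. Leaving out each animal in turn, HBB by region lay between -0.0182 (without animal 11) and 0.17 (without animal 7). For age in CA1, MBP lay between -0.11 (without animal 5) and 0.0293 (without animal 3), and WFS1 between -0.10 (without animal 4) and 0.0284 (without animal 5), with 0.01002 without animals 3 and 5. For age in DG, HBA lay between -0.38 (without animal 11) and 0.24 (without animal 1), with -0.41 without animals 3 and 5, and WFS1 between -0.0345 (without animal 8) and 0.0570 (without animal 3), with 0.0270 with array weights, 0.00555 with the animal as a random block, 0.0511 without animals 3 and 5 and 0.00371 with the actin ratio.

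Calls of single lists were also lost. Of 23 settings run for age in CA1, synaptic vesicle, immediate early and oxidative phosphorylation genes each lost theirs in 12, calcium handling in 9, endothelial in 6, complement and interferon response in 4, immature neuron in 3 and MHC in 2. Of 22 for age in DG, antioxidant genes lost theirs in 11, MHC in 3 and the other lists in 2. Of 22 for age by region, ribosomal protein genes lost theirs in 14, calcium handling in 9, oxidative phosphorylation and glycolysis in 7 and synaptic vesicle in 4. By region, no list lost its call in more than 3 of 23, and HBA lost its call without the replicate block and with the animal as a random block.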

Other observations

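The comparison with other probe sets of called genes was chosen after the values had been seen. Beyond the lists already described, age moved no further group past the threshold of camera. In CA1, 6 of 9 general neuron and axon genes had lower means in aged animals (camera adjusted p = 0.0844). Higher means were found for 9 of 11 myelin markers (adjusted p = 0.0844) and 9 of 12 lipid transport genes (adjusted p = 0.0844). These counts are of signs alone, and no member passed over all probe sets tested. In DG, 11 of 12 immediate early genes had lower means in aged animals and 11 of 12 endothelial markers had higher means. Both lists had a camera adjusted p of 0.106, and again no member passed over all probe sets tested. NEU4, a sialidase gene on the oligodendrocyte precursor list, had log2 changes of 0.70 ± 0.23 in CA1 and 0.54 ± 0.14 in DG, and S100B, a calcium-binding protein of astrocytes, had 0.29 ± 0.11 and 0.33 ± 0.10; these genes were singled out after their values were seen, and none passed for age in limma (adjusted p from 0.136 to 0.507). By region, astrocyte genes went both ways, with 4 of 14 lower in CA1, such as ALDH1L1 at 1.49-fold and SOX9 at 1.42-fold, and S100B higher by 1.20-fold.

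Many age calls rested on a single probe set of their gene. Of the 29 named genes with a called probe set, 20 had another tested probe set that was not called. The median over these genes of the other probe sets' change relative to the called change was 0.0817, and in 5 of the 20 the mean of the other probe sets had the opposite sign, though single ones among them did not always. Examples are TBC1D19 in CA1 (-1.88 on the called probe set and -0.19 on another), BTD in CA1 (0.93 and a mean of 0.17) and SERINC1 in DG (-0.96 and a mean of 0.11), which were chosen after their values were seen. A ratio near 0 is favoured by the choice itself, since the called probe sets were picked for their change and the others for not passing, so it does not show why the probe sets differ, and probe sequences were not used here.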
